A study of Homo sapiens with 6 samples.

How the data were processed

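The 6 libraries are total RNA of the FaDu cell line, 3 labelled siCtrl and 3 labelled siMFAP2. Per the labels' protocols, RNA was extracted with the RNAprep Pure Micro Kit and libraries were built with the MGIEasy RNA Library Prep Kit. The submitters' processing notes name Bowtie2, an aligner, RSEM, which estimates expression from aligned reads, and DESeq2, with the build GRCh38, and give no versions, roles or order. The gene annotation, the strand setting and the sequences of the siRNAs were not given in the sources used here.

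The deposited tables, 1 per library, give a gene identifier and a value without a unit in the header. The values deposited by the authors were taken as FPKM (fragments per kilobase of exon per mega-fragment). They are not whole numbers, the libraries sum to between 262609 and 272081, and within a library 57.8 to 59.8% of low values times the summed exon length of the gene were whole multiples of 1 step within 0.01. Those steps give the depth of each library: 13.54, 15.11 and 14.49 M (mega) reads for siCtrl replicates 1 to 3 and 16.76, 13.67 and 15.68 M for siMFAP2 replicates 1 to 3. At these depths 3 reads in a gene of 1000 bases equal 0.179 to 0.222 FPKM, and this floor covers counting error only. No library pair held identical values. Of 50868 gene identifiers, 50111 (98.51%) were found in GENCODE 29 on GRCh38, the build the processing notes name, which supplied exon lengths, coordinates, gene types and 3′ UTRs, and 49659 were found in a table of current gene symbols.

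Samples were grouped by their titles. The single comparison was siMFAP2 against siCtrl. Genes with at least 0.1 FPKM in at least 3 libraries were tested, 17846 in all, on log2(FPKM + 1) with limma 3.58.1 (trend and robust empirical Bayes, statmod 1.5.0, R 4.3.3) in a model with the group only and 4 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. The design written before the data were examined planned a test on counts, with limma on log2 values if the files held normalized values, and the latter applied. Values are given as means with SD over 3 libraries. For a single gene, an exact permutation test of 3 against 3 libraries cannot give a two-sided p below 0.1. Over all tested genes, 29.3% had groups that did not overlap, against 10% by chance.

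The 31 gene lists were fixed before the data were examined, from textbook knowledge. Each was tested with camera at a preset correlation of 0.01, with camera at a correlation estimated from the data, and with fry, adjusted over the lists. Of the 31 lists, 11 were called by camera and 16 by fry. With the estimated correlation camera called 0 after adjustment, and 5 lists had an unadjusted p under 0.05. For each list the called members are counted from the adjustment over all genes and again adjusted over the list alone. In the Wnt pathway components, the elastic fibre genes, the matrix proteases, the G1/S genes, the p53 targets, the apoptosis regulators and the RNA interference genes, the median was below 0 while the camera direction was up.

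The rule for named genes, also fixed beforehand, took MFAP2; CTNNB1, MYC, CCND1, AXIN2, LEF1 and TCF7; the 12 largest changes in each direction with an adjusted p under 0.05, a mean log2(FPKM + 1) of at least 1, groups that did not overlap and an established symbol; the 3 smallest p in each direction; up to 4 called members per list by p; and, in a list without a call, the 2 members with the highest means. The floor on the mean was planned in CPM (library-size-scaled counts) and was applied to log2(FPKM + 1). Of these genes, 113 were called, and the text names a part of them. Some genes that the rule took are not reported here. SRP9, PTPRC, AC139530.2, MRPL12, SLC25A10, IFNL1, IFNB1 and CXCL10 were added after their values were seen. RAC2, ITGB2, CD53, CD52, TYROBP and AIF1 also lie outside the rule. They are named from the test of immune-cell RNA, which was chosen after the results were seen.

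Alternatives planned beforehand were median-of-ratios, upper-quartile and equal-sum scaling, no filter, a filter of 1 FPKM in all libraries of a group, a pseudocount of 0.1, the replicate number as a block, non-robust moderation, leaving out each library, an adjusted p of 0.01 and a test against a fold of 1.5. Added later were limma-voom on reads estimated from FPKM, exon length and depth, equal sums over nuclear protein-coding genes, and nuclear protein-coding genes alone.

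The procedure was tested on simulated data. Reads were drawn for the real genes from the real means and depths with a dispersion of 0.005. That dispersion was set to the same value for every gene and was not estimated from these libraries. The recovery and the false calls therefore do not cover genes with a wider spread. Known folds were applied to 200 genes, all drawn from those with a mean of at least 1 FPKM. Genes below that mean, as MFAP2 is, were not changed, so the recovery does not cover them. Of 17256 simulated genes tested for siMFAP2 against siCtrl, limma recovered 8% of the genes changed 1.25-fold, 64% of those changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold, with 9 false calls, and it made 0 calls when no gene was changed. The median absolute log2 fold change estimated for genes changed 2-fold was 0.80.

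For the closing tests, the longest annotated 3′ UTR of each tested protein-coding gene (12599 of 12887 had one of at least 50 bases) was searched for every sequence of 7 bases. The fold change was regressed on the presence of each of 16163 sequences with log UTR length, GC content and mean expression, each with its square, as covariates, and compared with 1000 permutations of the covariate-adjusted fold changes over genes (numpy 2.4.6, scipy 1.17.1, Python 3.11.15). In simulated data the scan over these genes recovered 5 of 5 planted sequences. The planted shift was larger than the observed difference in medians, which were -0.0747 with GACAAGT and -0.0115 without it. The recovery therefore does not cover an effect as small as the observed one. Figures were drawn with matplotlib 3.10.9.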

Results

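RNA was sequenced from FaDu, an established cell line from a human squamous carcinoma of the hypopharynx. The 6 libraries formed 2 groups of 3. The siCtrl libraries came from cells given a control small interfering RNA (siRNA) and the siMFAP2 libraries from cells given an siRNA against MFAP2, which encodes a glycoprotein of the microfibrils that surround elastic fibres. Expression was given in FPKM for 50868 genes, of which 24707 were at 0 in every library. The FPKM of a library summed to between 262609 and 272081, and between 10822 and 11005 genes reached 1 FPKM. The values pointed to depths of 13.54 to 16.76 M (mega) reads per library, at which 3 reads in a gene of 1000 bases came to between 0.179 and 0.222 FPKM, a floor that covers counting error only. Correlations of log2(FPKM + 1) across genes were 0.989 to 0.990 between libraries of one group and 0.984 to 0.986 between groups, and genes are not independent replicates. The labels did not say whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these libraries.

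MFAP2 itself was low in FaDu cells. In the order of replicates 1 to 3, it stood at 0.22, 0.509 and 0.565 FPKM in siCtrl and at 0.059, 0.145 and 0.126 FPKM in siMFAP2, so that every siMFAP2 library lay below every siCtrl library. The means were 0.431 ± 0.185 and 0.110 ± 0.0452 FPKM (SD, n = 3), a ratio of 3.91. MFAP2 (ENSG00000117122) lies on chromosome 1 at 16974502 to 16980835, minus strand, in GRCh38. Its values correspond to an estimated 8.7 to 23.9 reads in siCtrl and 2.9 to 5.8 reads in siMFAP2, and the smallest whole numbers of reads in the ratios of the values are 12, 31 and 33 in siCtrl and 4, 8 and 8 in siMFAP2. On the log2(FPKM + 1) scale, which understates the change of a low gene, the MFAP2 log2 fold change was -0.36 with a standard error of 0.106 and a limma adjusted p of 0.103, which did not pass the threshold of 0.05. Without siCtrl replicate 1 it was -0.47 with an adjusted p of 0.0431.

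Cells given the MFAP2 siRNA had 560 genes higher and 592 genes lower than control cells, out of 17846 tested. Which direction held more genes depended on the scaling. Under median-of-ratios scaling 649 were higher and 513 lower, and scaled to nuclear protein-coding genes 527 and 608. On the log2(FPKM + 1) scale, which understates folds, most in low genes, the median absolute log2 fold change of the 1152 changed genes was 0.41. On that scale 23 genes changed at least 2-fold, 9 up and 14 down. LYPD3 and HSDL2, whose mean FPKM rose more than 2-fold, stayed under that cut. A pseudocount of 0.1 or limma-voom on estimated reads gave more such genes. Among the genes that rose most were the basement membrane collagen COL4A1, the antiviral gene RSAD2, the actin-binding tropomyosin TPM4 and the chemokine CXCL8. Of genes with an established symbol, those that fell most included MARCKSL1, an actin-regulating protein, the stathmin STMN3, the trafficking protein STX6, the glycosyltransferase GALNT7, the imprinted gene MEST, the homeobox gene HOXA10 and the neurotrophin receptor NGFR. COL4A1 rose from 2.30 ± 0.0416 to 6.32 ± 0.292 FPKM (SD, n = 3), a log2 fold change of 1.15 with a limma adjusted p of 0.000801. RSAD2 rose from 1.22 ± 0.179 to 3.97 ± 0.443 FPKM and TPM4 from 18.3 ± 2.14 to 38.3 ± 2.73 FPKM. CYSRT1 rose from 25.8 ± 1.13 to 52.8 ± 1.90 FPKM, LYPD3 from 10.3 ± 0.617 to 21.6 ± 2.76 FPKM and HSDL2 from 3.66 ± 0.141 to 8.22 ± 0.564 FPKM. MARCKSL1 fell from 36.9 ± 0.908 to 13.6 ± 0.898 FPKM, a log2 fold change of -1.38 with a limma adjusted p of 0.000582. STMN3 fell from 3.77 ± 0.266 to 0.968 ± 0.243 FPKM, STX6 from 7.45 ± 0.2198 to 2.54 ± 0.186 FPKM, GALNT7 from 6.68 ± 0.431 to 2.41 ± 0.327 FPKM and MEST from 11.9 ± 0.559 to 4.86 ± 0.509 FPKM. HOXA10 fell from 4.30 ± 0.160 to 1.57 ± 0.406 FPKM, NGFR from 14.02 ± 1.79 to 6.203 ± 0.646 FPKM and NIPSNAP2 from 10.3 ± 0.386 to 4.50 ± 0.841 FPKM. By p-value, PCNX3 also stood out among the higher genes, at 27.2 ± 0.197 and 45.9 ± 1.04 FPKM, and SYNGR2 among the lower ones, at 21.9 ± 0.458 and 11.1 ± 0.197 FPKM. The longest annotated 3′ UTRs of GALNT7, HOXA10, NIPSNAP2 and SYNGR2 hold the sequence GACAAGT, which MFAP2 transcripts also hold, and those of TPM4, HSDL2 and PCNX3 hold TCGGAGA, as SYNGR2 also does. In limma, leaving out siCtrl replicates 1, 2 and 3 in turn gave 480, 477 and 490 changed genes, and leaving out siMFAP2 replicates 1, 2 and 3 gave 622, 523 and 380. In these fits 178 to 297 genes were higher and 202 to 325 lower, and without siMFAP2 replicate 1 there were 38 genes changed at least 2-fold. CXCL8, at 8.77 ± 1.77 and 19.1 ± 2.70 FPKM, was no longer called without siMFAP2 replicate 2 or 3, with an adjusted p of up to 0.0587.

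**Figure D1:**
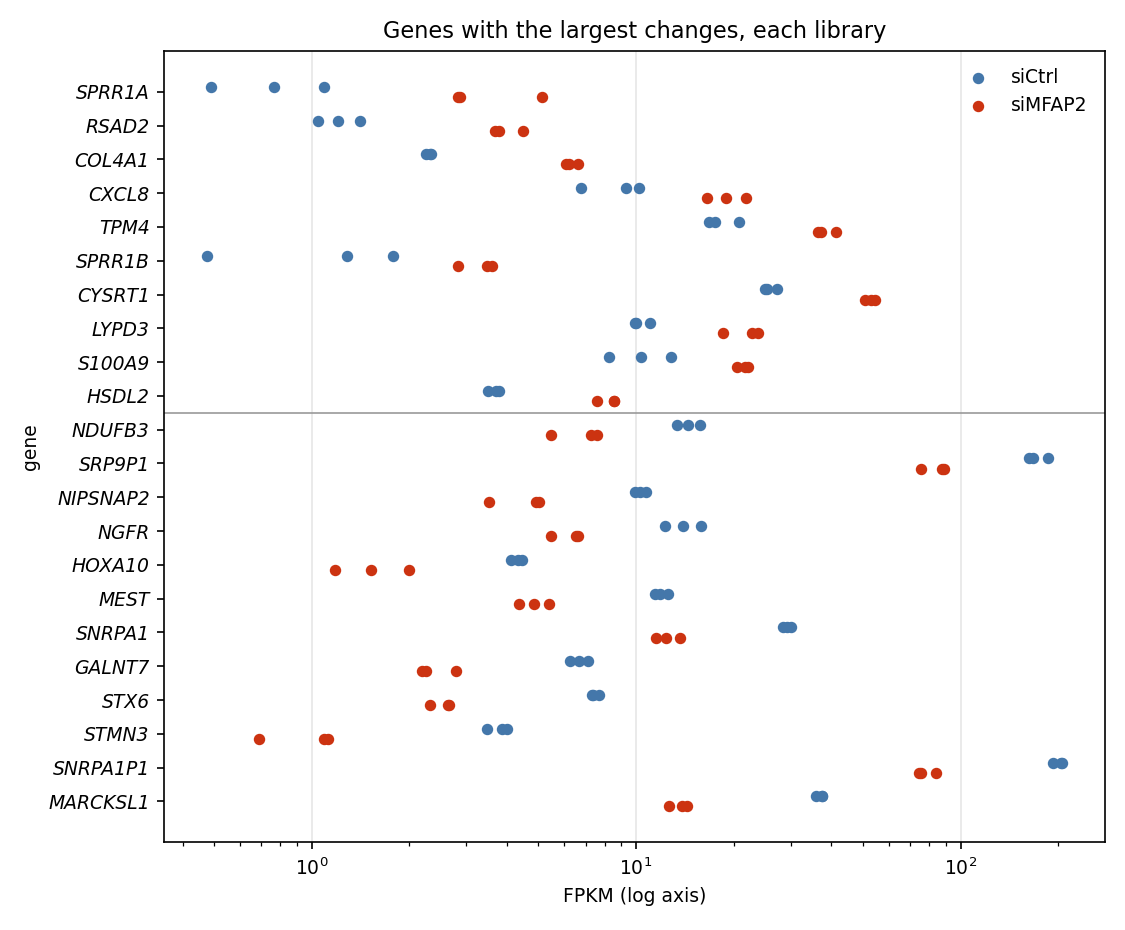
FPKM of 10 of the 12 genes with the largest rise (above the line) and the 12 with the largest fall (below it) among genes that the rule for named genes could take, which skips clone-based names such as AC139530.2, on a log axis, with 1 point per library and 3 libraries per group. In each gene the siCtrl and siMFAP2 libraries do not overlap, as the rule that chose the genes required. COL4A1 averaged 2.30 FPKM in siCtrl and 6.32 FPKM in siMFAP2, and MARCKSL1 averaged 36.9 and 13.6 FPKM.

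The title of the series names β-catenin signaling, and its called targets moved in both directions after the MFAP2 knockdown. CCND1, the cyclin that drives entry into the cell cycle and a target of β-catenin, fell from 231.6 ± 2.21 to 163.6 ± 10.3 FPKM (SD, n = 3), a log2 fold change of -0.50 with a limma adjusted p of 0.00558. DKK1, a secreted Wnt inhibitor that is itself a target, fell from 42.8 ± 2.39 to 31.4 ± 1.20 FPKM. The AP-1 subunit JUN, another target, whose 3′ UTR holds GACAAGT, rose from 27.5 ± 0.975 to 41.7 ± 1.78 FPKM. CTNNB1, which encodes β-catenin, stood at 27.07 ± 1.09 and 29.05 ± 1.10 FPKM, with a log2 fold change of 0.10 and an adjusted p of 0.313. Of 30 targets tested, 3 rose and 3 fell, and adjusted over the list alone the counts were 3 and 5. Called or not, 9 targets had a positive fold change and 21 a negative one. EPHB3, at 3.17 ± 0.120 and 2.07 ± 0.196 FPKM, was among the lower ones but, of the 6 fits that left out 1 library, kept its call only without siMFAP2 replicate 3, with an adjusted p of up to 0.0640. In those fits 1 to 2 targets were higher and 2 to 3 lower. The median log2 fold change of the targets was -0.08, and the camera test against all other genes gave an adjusted p of 0.289, or an adjusted p of 0.519 with an estimated correlation. The fry test of a shared direction gave an adjusted p of 0.0593, and its test for change in either direction gave an adjusted p of 2.78e-05. The latter was not particular to these targets. It also passed for every other list except the immune cell markers (fry adjusted p of 0.111). For the G1/S genes it gave 9.15e-06 and for the RNA interference genes 3.70e-05. MYC stood at 0.568, 0.546 and 11.02 FPKM in siCtrl and at 0.519, 0.359 and 0.448 FPKM in siMFAP2, so its mean difference rested on siCtrl replicate 3. The MYC log2 fold change was -1.10 with an adjusted p of 0.468, and -0.11 with an adjusted p of 0.521 without that library. LEF1, at 0.283 ± 0.0756 and 0.202 ± 0.0508 FPKM, and TCF7, at 0.265 ± 0.0686 and 0.353 ± 0.164 FPKM, did not pass the test. AXIN2 lay between 0.017 and 0.059 FPKM in all 6 libraries, below the filter. CCND1 (ENSG00000110092) lies on chromosome 11 at 69641087 to 69654474 and CTNNB1 (ENSG00000168036) on chromosome 3 at 41194741 to 41260096.

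Among 52 components of the Wnt pathway, 8 rose and 4 fell, and adjusted over the list alone the counts were 10 and 7. In the 6 fits without 1 library, 2 to 3 were higher and 0 to 4 lower. The repressor TCF7L1 rose from 2.90 ± 0.183 to 4.70 ± 0.222 FPKM and the ligand WNT7B from 25.6 ± 1.17 to 34.9 ± 1.247 FPKM (SD, n = 3). PORCN, the acyltransferase that modifies Wnt ligands, fell from 2.99 ± 0.160 to 1.85 ± 0.129 FPKM, and its limma adjusted p of 0.0110 became 0.0513 without siMFAP2 replicate 3. The median of the components was -0.05 while the camera direction was up, with an adjusted p of 0.727.

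**Figure D2:**
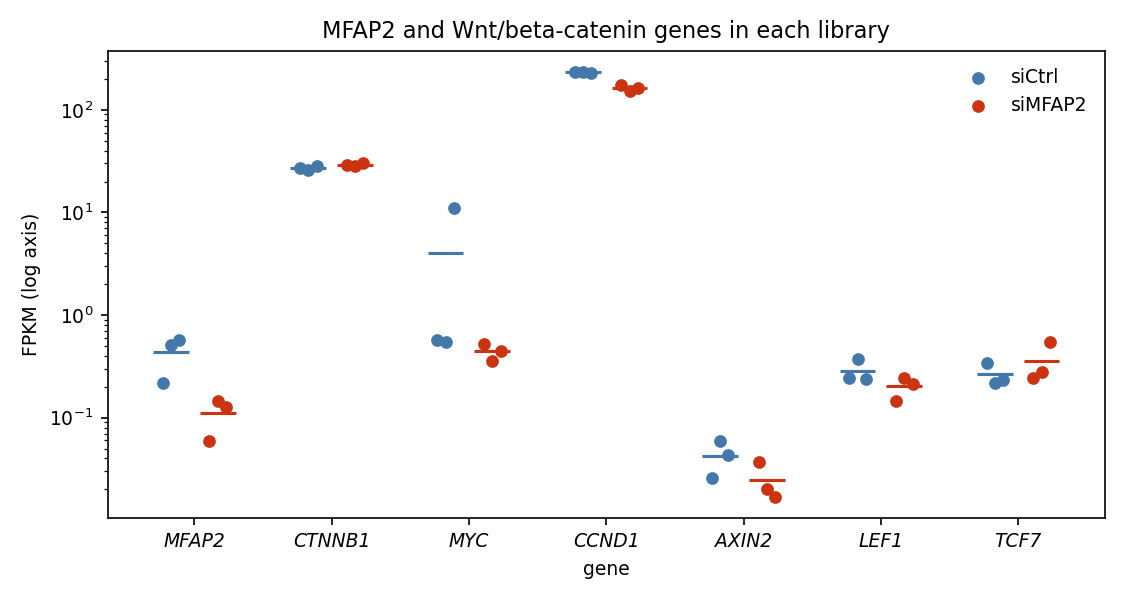
FPKM of MFAP2 and of 6 genes of the Wnt/β-catenin pathway on a log axis, with 1 point per library and a bar at the mean of the 3 libraries of a group. MFAP2 averaged 0.431 FPKM in siCtrl and 0.110 FPKM in siMFAP2, CCND1 averaged 231.6 and 163.6 FPKM, and the siCtrl mean of MYC rested on 1 library at 11.02 FPKM.

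Many interferon-stimulated genes, which cells switch on in antiviral defence, rose in siMFAP2. Of 37 tested, 16 rose and 0 fell, 34 had a positive fold change, and adjusted over the list alone the counts were 23 and 0. IFIT3 rose from 41.6 ± 1.62 to 74.9 ± 2.35 FPKM, OASL from 31.3 ± 1.88 to 56.3 ± 2.24 FPKM and IFIT1 from 8.22 ± 0.506 to 14.5 ± 0.760 FPKM (SD, n = 3). The median log2 fold change of the list was 0.40, and camera gave an adjusted p of 5.47e-18, or an adjusted p of 0.212 with an estimated correlation. In limma fits without 1 library each, between 10 and 13 of these genes rose and 0 fell, and at an unadjusted p under 0.05, 4019 of all genes tested differed in either direction. Of 25 NF-κB and cytokine genes, 7 rose and 0 fell, and adjusted over the list alone the counts were 11 and 1. PTGS2, the inducible cyclooxygenase, rose from 0.569 ± 0.134 to 2.04 ± 0.229 FPKM, the cytokine IL1B from 17.6 ± 1.40 to 28.1 ± 1.90 FPKM and the chemokine CXCL1 from 9.06 ± 0.990 to 15.8 ± 1.42 FPKM. Camera gave this list an adjusted p of 0.000517, or an adjusted p of 0.239 with an estimated correlation, and in the fits without 1 library 3 to 6 members rose and 0 to 1 fell. Of 27 immediate early and AP-1 genes, 4 rose and 0 fell, and adjusted over the list alone the counts were 7 and 1. Camera gave an adjusted p of 0.00418, or an adjusted p of 0.239 with an estimated correlation. The 4 were PHLDA1, the phosphatases DUSP1 and DUSP5 and the transcription factor ETV4, with 0 to 4 called in the fits without 1 library. DUSP5 and ETV4 kept their limma calls only without siMFAP2 replicate 1, with adjusted p of up to 0.107 and 0.115, DUSP1 only without that library or siCtrl replicate 2 (up to 0.0984), and PHLDA1 only without siCtrl replicate 3 or siMFAP2 replicate 2 (up to 0.0607). Of the 15 markers of immune cells, only CD68 and CD14 passed the filter, and both rose, which was also the count adjusted over the list alone. CD68 went from 3.20 ± 0.594 to 6.09 ± 0.180 FPKM and CD14 from 1.50 ± 0.0427 to 2.13 ± 0.103 FPKM, with a camera adjusted p of 0.00566, or an adjusted p of 0.212 with an estimated correlation. Without a filter on low values, the median log2 fold change of immune cell markers was 0.01 with an adjusted p of 0.0588. Their calls were lost without siMFAP2 replicate 3 (CD68, adjusted p of 0.0507) and in all 6 such fits (CD14, up to 0.104). The pan-leukocyte marker PTPRC was at 0.007 FPKM in siCtrl replicate 2 and listed at 0 in the other 5 libraries.

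Some collagen genes also rose. Of 31 collagens, laminins and integrins, 9 rose and 1 fell, and adjusted over the list alone the counts were 13 and 1. Beside COL4A1, its partner chain COL4A2 rose from 6.33 ± 0.179 to 9.87 ± 0.285 FPKM and COL17A1, a collagen of hemidesmosomes, from 28.5 ± 0.243 to 49.6 ± 2.25 FPKM (SD, n = 3). The integrin β1 gene ITGB1, whose 3′ UTR holds GACAAGT, fell from 30.8 ± 3.97 to 17.3 ± 1.41 FPKM. Camera gave the list an adjusted p of 0.000271, or an adjusted p of 0.239 with an estimated correlation, and in the 6 limma fits without 1 library 3 to 5 members rose and 1 fell. Of 20 YAP/TAZ targets, 6 rose and 3 fell, and adjusted over the list alone the counts were 7 and 3. In those 6 fits 2 to 4 of these targets rose and 1 to 3 fell, with 2 and 1 without siMFAP2 replicate 3. The tissue factor gene F3 rose from 182.8 ± 10.95 to 320.7 ± 7.94 FPKM and the receptor kinase AXL from 18.8 ± 1.49 to 27.7 ± 0.582 FPKM, while FOXF2, which also holds GACAAGT in its 3′ UTR, fell from 8.06 ± 0.591 to 5.18 ± 0.342 FPKM. The median log2 fold change of YAP/TAZ targets was 0.10, with a camera adjusted p of 0.0346, or an adjusted p of 0.4002 with an estimated correlation. The adjusted p was 0.0597 without siMFAP2 replicate 1, 0.0514 without a filter, 0.0862 with a stricter filter and 0.0556 over nuclear protein-coding genes. Of 27 matrix proteases and inhibitors, 3 rose and 1 fell (4 and 2 adjusted over the list alone), with the inhibitor TIMP2 going from 1.87 ± 0.117 to 0.864 ± 0.0589 FPKM. Of 21 TGF-β and SMAD targets, 4 rose and 1 fell (4 and 3 adjusted over the list alone), among them BHLHE40, which rose from 38.3 ± 0.551 to 51.03 ± 1.78 FPKM. Of 14 mesenchymal markers, 3 rose and 0 fell (4 and 1 adjusted over the list alone). AXL was among them, and SNAI2, at 9.70 ± 2.26 and 17.8 ± 1.28 FPKM, kept its limma call only without siCtrl replicate 2 among the fits without 1 library, with an adjusted p of up to 0.0943. Of 15 genes of elastic fibres and microfibrils, the structures that MFAP2 belongs to, 1 rose and 0 fell (also adjusted over the list alone). This was LTBP3, at 7.41 ± 0.235 and 9.001 ± 0.339 FPKM, whose limma adjusted p of 0.0428 was up to 0.135 in the 6 fits without 1 library, and which was not called without a filter or when libraries were scaled to nuclear protein-coding genes. Camera gave these last 4 lists adjusted p of 0.667, 0.431, 0.368 and 0.727, while fry gave both the TGF-β targets and the mesenchymal markers an adjusted p of 0.0181 (up). In the limma fits without 1 library, 1 to 3 matrix proteases rose and 1 fell, 2 to 3 TGF-β targets rose and 0 to 1 fell, 1 to 2 mesenchymal markers rose and 0 to 1 fell, and 0 elastic fibre genes were called. Of the 4 fibroblast and 3 endothelial markers tested none passed the limma test. ACTA2, at 0.848 ± 0.0862 and 1.27 ± 0.120 FPKM, and CDH5, whose 3′ UTR holds GACAAGT, at 0.742 ± 0.112 and 0.422 ± 0.0318 FPKM, were among them. Adjusted over the list alone, the fibroblast list had 1 higher and 0 lower and the endothelial list 0 higher and 1 lower, against 0 in either direction over all genes. Camera gave the fibroblast list an adjusted p of 0.0924 and the endothelial list 0.368.

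The receptors NOTCH1, NOTCH2 and NOTCH3 and some basal squamous genes fell. Of 19 genes of the Notch pathway, 6 fell and 0 rose, and adjusted over the list alone the counts were 8 and 1. The receptor NOTCH1 fell from 21.8 ± 0.141 to 13.1 ± 0.339 FPKM, a log2 fold change of -0.69 with a limma adjusted p of 0.00153, and NRARP, a target of Notch that limits its signal, from 95.98 ± 8.85 to 58.8 ± 2.71 FPKM (SD, n = 3). NOTCH2, at 16.5 ± 0.252 and 11.7 ± 0.971 FPKM, and the ligand DLL1, at 12.6 ± 0.147 and 8.74 ± 0.826 FPKM, were called with all 6 libraries but not without siMFAP2 replicate 3 or siCtrl replicate 3, with an adjusted p of up to 0.0561 and 0.0571, and DLL1 not without siCtrl replicate 1 or 2 either. Camera gave an adjusted p of 0.00703, or an adjusted p of 0.212 with an estimated correlation, and 2 to 4 members fell in the 6 limma fits without 1 library. Of 20 basal squamous genes, 7 fell and 0 rose, and adjusted over the list alone the counts were 12 and 2. NOTCH3 fell from 10.2 ± 0.255 to 5.004 ± 0.301 FPKM and TFAP2C, whose 3′ UTR holds GACAAGT, from 8.78 ± 0.307 to 5.76 ± 0.476 FPKM. For this list camera gave an adjusted p of 0.00418, or an adjusted p of 0.212 with an estimated correlation, and 2 to 4 members fell and 0 to 1 rose in the limma fits without 1 library. Of 27 epithelial junction genes, 2 rose and 4 fell (2 and 5 adjusted over the list alone). PERP, a desmosome component, rose from 160.4 ± 5.65 to 242.9 ± 8.54 FPKM, and the tight junction gene CLDN1, at 75.5 ± 3.46 and 46.05 ± 6.80 FPKM, lost its limma call without siCtrl replicate 2, siCtrl replicate 3 or siMFAP2 replicate 3, with an adjusted p of up to 0.0627. Of 21 keratinocyte differentiation genes, 5 rose and 2 fell, also adjusted over the list alone. KRT4 fell from 50.2 ± 1.57 to 31.3 ± 3.17 FPKM. S100A9, at 10.5 ± 2.27 and 21.5 ± 0.863 FPKM, and SPRR1A, at 0.784 ± 0.302 and 3.62 ± 1.32 FPKM, had large fold changes of 0.99 and 1.35 on the log2 scale. S100A9 was not called without siMFAP2 replicate 3 (adjusted p of 0.0561) and SPRR1A not without siCtrl replicate 2 or 3 (adjusted p of up to 0.0642). Camera gave the junction genes an adjusted p of 0.668 and the differentiation genes 0.285, and fry gave 0.0394 (down) and 0.00236 (up). In the limma fits without 1 library, 1 to 2 junction genes rose and 0 to 2 fell, and 1 to 3 differentiation genes rose and 1 to 2 fell. Only 1 differentiation gene rose without siCtrl replicate 2 or siMFAP2 replicate 3, and under each of the 4 other scalings 1 fell. Under 3 of those scalings 1 Notch gene rose.

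**Figure D3:**
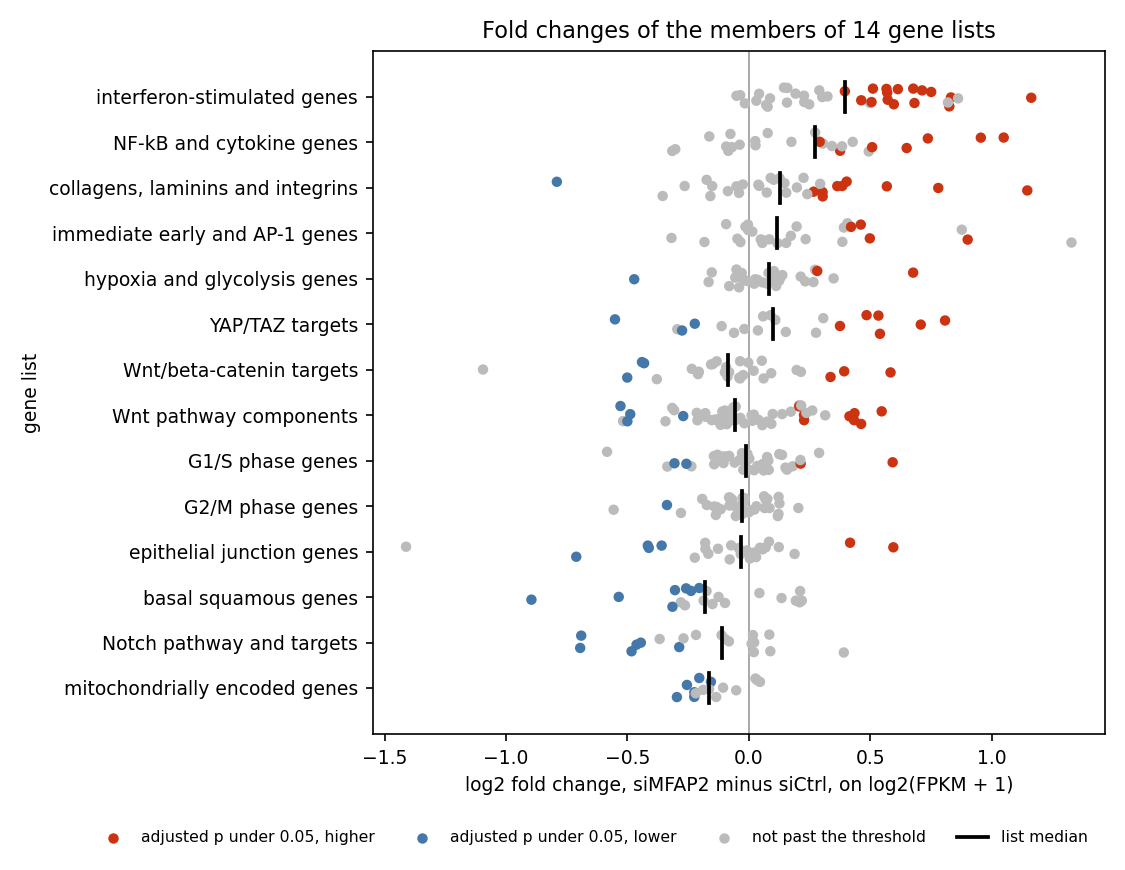
Log2 fold change of each tested member of 14 gene lists, siMFAP2 minus siCtrl, on the log2(FPKM + 1) scale. Coloured points passed an adjusted p of 0.05 in limma (red higher, blue lower), grey points did not, and black bars are list medians. The interferon-stimulated genes have a median of 0.40 with 16 members higher and 0 lower, and the Wnt/β-catenin targets a median of -0.08 with 3 higher and 3 lower.

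In lists of proliferation, p53 and apoptosis genes, most members were not called. Those called were 4 of 40 G1/S genes, 1 of 40 G2/M genes, 4 of 25 p53 targets and 5 of 22 apoptosis regulators. Over all genes 1152 of 17846 were called. Of 40 G1/S genes, 2 rose and 2 fell (3 and 2 adjusted over the list alone), and of 40 G2/M genes, 0 rose and 1 fell (also adjusted over the list alone). The transcription factor E2F1 rose from 20.4 ± 0.309 to 31.4 ± 2.12 FPKM (SD, n = 3). HMMR, the G2/M gene, stood at 6.65 ± 0.435 and 5.05 ± 0.0989 FPKM and lost its limma call in each of the 6 fits without 1 library, with an adjusted p of up to 0.0966. Of 25 p53 targets, 2 rose and 2 fell (4 and 3 adjusted over the list alone), and CDKN1A, at 14.95 ± 1.30 and 20.3 ± 1.54 FPKM, kept its call only without siMFAP2 replicate 1, with an adjusted p of up to 0.112. Of 22 apoptosis regulators, 4 rose and 1 fell (also adjusted over the list alone). Of 29 replication-dependent histone genes, 0 rose and 3 fell (also adjusted over the list alone), and H3C10, at 2.29 ± 0.301 and 1.05 ± 0.277 FPKM, kept its call only without siMFAP2 replicate 2, with an adjusted p of up to 0.0756. Camera gave the G1/S, G2/M and p53 lists an adjusted p of 0.727 and the apoptosis regulators 0.245, while fry gave the apoptosis regulators 0.0361 (up) and the histones 0.00337 (down). In the limma fits without 1 library, 1 G1/S gene rose and 0 to 1 fell, 0 to 1 p53 targets rose and 0 fell, 2 to 3 apoptosis regulators rose and 0 to 1 fell, and 0 to 1 histone genes fell. Scaled to nuclear protein-coding genes, 1 G1/S gene rose. The median log2 fold change of replication-dependent histone genes was -0.15 with a camera adjusted p of 0.0761, or an adjusted p of 0.239 with an estimated correlation. At the preset correlation it was 0.0470 without siCtrl replicate 1, 0.0306 without siMFAP2 replicate 3, 0.0412 under median-of-ratios scaling and 0.0395 with equal library sums. Of 13 genes of the RNA interference machinery, 1 rose and 0 fell (1 and 1 adjusted over the list alone), with a camera adjusted p of 0.9002. This was TNRC6A, at 8.19 ± 0.210 and 10.9 ± 0.347 FPKM, whose limma adjusted p was 0.0548 without siMFAP2 replicate 3.

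Among metabolic genes, HK2, the first enzyme of glycolysis, rose from 12.1 ± 0.589 to 20.002 ± 0.410 FPKM, while PGAM1, a later enzyme, fell from 107.8 ± 2.94 to 77.4 ± 2.35 FPKM (SD, n = 3). Of 31 hypoxia and glycolysis genes, 2 rose and 1 fell (3 and 1 adjusted over the list alone), with a camera adjusted p of 0.0172, or an adjusted p of 0.212 with an estimated correlation. The median log2 fold change of hypoxia and glycolysis genes was 0.08, and the camera adjusted p was 0.0717 without siMFAP2 replicate 2 and 0.0564 with a stricter filter. In the limma fits without 1 library, 1 to 2 of them rose and 1 fell. The stress gene PPP1R15A rose from 5.86 ± 0.377 to 9.44 ± 0.340 FPKM. PGD, an enzyme of the pentose phosphate pathway, fell from 67.4 ± 1.97 to 52.1 ± 0.826 FPKM, and the complex I subunit NDUFB3 from 14.5 ± 1.18 to 6.77 ± 1.14 FPKM. Of 30 genes of the unfolded protein and integrated stress responses, 2 rose and 2 fell (6 and 6 adjusted over the list alone), and of 32 cholesterol and fatty acid synthesis genes, 1 rose and 1 fell (2 and 3). Of 31 oxidative phosphorylation genes, 2 rose and 1 fell (3 and 3 adjusted over the list alone), and of 22 antioxidant NRF2 targets, 4 rose and 4 fell (8 and 5). Camera gave these 4 lists adjusted p of 0.667, 0.549, 0.727 and 0.447. In the fits without 1 library, 1 to 2 stress genes rose and 0 to 1 fell, 1 cholesterol gene rose and 0 to 1 fell, 0 oxidative phosphorylation genes rose and 1 fell, and 0 to 3 NRF2 targets rose and 1 to 4 fell, with 0 and 1 without siMFAP2 replicate 3. Under median-of-ratios scaling 2 cholesterol genes rose. Of 40 cytosolic ribosomal protein genes, 1 rose and 0 fell (also adjusted over the list alone), the median log2 fold change of cytosolic ribosomal protein genes was 0.06, and camera gave an adjusted p of 0.00418, or an adjusted p of 0.596 with an estimated correlation. The one called gene was RPL11, at 251.0 ± 15.4 and 314.0 ± 7.16 FPKM, which kept its limma call only without siCtrl replicate 1 or 3, with an adjusted p of up to 0.0713. The camera adjusted p of the list was 0.221 without siMFAP2 replicate 2, and fry gave 0.292. With equal library sums 2 ribosomal protein genes rose. Of 15 mitochondrially encoded genes, 0 rose and 6 fell (0 and 8 adjusted over the list alone), with MT-CO1 going from 8888 ± 198 to 7238 ± 209 FPKM. Camera gave an adjusted p of 0.00195, or an adjusted p of 0.508 with an estimated correlation, and 1 to 5 members fell in the limma fits without 1 library. Under median-of-ratios and upper-quartile scaling 3 members fell, and with equal library sums 4. All genes with a symbol that starts with MT-, in the list or not, took 24.4, 23.3 and 23.7% of all FPKM in siCtrl and 22.1, 21.2 and 21.0% in siMFAP2.

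Some of the largest values belonged to genes that share sequence with another. The splicing factor gene SNRPA1 fell from 29.2 ± 0.904 to 12.51 ± 1.09 FPKM and its processed pseudogene SNRPA1P1 from 200.9 ± 6.72 to 78.2 ± 5.35 FPKM (SD, n = 3), so reads of one could be counted in the other. SRP9P1 fell from 171.9 ± 12.48 to 84.03 ± 7.24 FPKM, while its parent gene SRP9 stood at 42.03, 41.04 and 39.05 FPKM in siCtrl and at 39.9, 18.5 and 15.8 FPKM in siMFAP2, with a limma adjusted p of 0.188. AC139530.2, outside the rule for named genes and singled out after its values were seen, was at 35.3, 31.4 and 37.0 FPKM in siCtrl and listed at 0 in the 3 siMFAP2 libraries. It spans chromosome 17 at 81703371 to 81720539, plus strand, and overlaps MRPL12 (81703357 to 81707526) and SLC25A10 (81712236 to 81721016) on that strand. MRPL12 was at 123.4 ± 2.94 FPKM in siCtrl and 177.0 ± 8.35 FPKM in siMFAP2, with a limma adjusted p of 0.00327, and SLC25A10 at 11.6 ± 1.96 and 15.6 ± 1.24 FPKM, with an adjusted p of 0.103. HOXA10 overlaps HOXA9, and NIPSNAP2 overlaps MRPS17, on the same strand, and their values carry the same uncertainty.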

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

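The tests chosen after the data were seen are limma-voom on estimated reads, the scaling to nuclear protein-coding genes and the fit of those genes alone; the others were planned. The count tests planned for edgeR and DESeq2 were not run, since the values are not counts. With 3 libraries per group and small fold changes on the log2(FPKM + 1) scale, the number of calls depended on the setting. Without a filter, over 26161 genes, 702 genes changed (357 higher, 345 lower), 691 of them among the 1152. At an adjusted p of 0.01, 260 changed. Leaving out 1 library gave 380 to 622 changed genes, 178 to 297 higher and 202 to 325 lower, in fits with fewer samples. Same-numbered libraries did not deviate together (correlations of 0.034, -0.057 and -0.012), and with the replicate block 250 genes changed (132 higher, 118 lower), 246 of them among the 1152, which costs degrees of freedom. The genes changed at least 2-fold, 23 in all, became 154 with a pseudocount of 0.1 and 186 by limma-voom on estimated reads, both of which damp low genes less, 6 in a test against a fold of 1.5, and 22 to 38 when 1 library was left out, the highest without siMFAP2 replicate 1. The MFAP2 fold change lay between -0.47 and -0.29 when 1 library was left out, and passed the threshold without siCtrl replicate 1; the cause was not tested. Under every other scaling the median of all genes moved by at most 0.014, but the balance of calls shifted. Higher genes made up 48.6% of calls in the main fit. They made up 55.9, 52.7 and 55.4% under median-of-ratios, upper-quartile and equal-sum scaling, and 46.4% scaled to nuclear protein-coding genes. The median of the Wnt/β-catenin targets stayed on its side of the threshold under every alternative run. Of 2612 further values of single genes and lists under alternatives, 0 reversed, 2255 stayed on their side of the threshold, 342 lost a call and 15 gained one. Of the losses, 296 came from the block or from leaving out a library. A change of sign was counted as a reversal only where the main value or the alternative passed the threshold. Most single genes were chosen because they were called, many also for groups that did not overlap, so this count does not test how stable directions are. Of the 113 called genes that the rule named, 55 kept their call in all 6 fits without 1 library. All 11 list calls were lost with an estimated correlation. Depth limits AXIN2, at an estimated 1.4 to 4.7 reads per library, and MFAP2 in siMFAP2, at 2.9 to 5.8 reads; the smallest whole numbers in the ratios of the values are higher, 3 to 10 and 4 to 8.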

Other observations

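The tests of immune-cell RNA, of library scaling and of other splits of the libraries, and the choice of IFNL1, IFNB1 and CXCL10, came after the results were seen; the tests of shared 3′ UTR sequences were chosen before theirs were seen. The interferon genes themselves were low. IFNL1, a type III interferon, was at 1.21, 0.154 and 0.483 FPKM in siCtrl and 1.60, 1.36 and 2.38 FPKM in siMFAP2, with a limma adjusted p of 0.113. IFNB1 was listed at 0 in all 6 libraries. CXCL10, a chemokine induced by interferon, was listed at 0 in the 3 siCtrl libraries and at 0.355, 0.249 and 0.108 FPKM in siMFAP2, with an adjusted p of 0.0831.

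The genes lower in siMFAP2 share a short sequence in their 3′ UTRs. Of all sequences of 7 bases, GACAAGT had the lowest covariate-adjusted t, -13.566 against a lowest value of -5.947 in 1000 permutations; 113 of 509 searched lower genes (22.2%) held it, against 7.9% of genes not called and 5.0% of higher genes, as did 21 of the 50 with the most negative fold change (42.0%), and genes where A follows it had a median log2 fold change of -0.10. The sequence also occurs in 3 of 6 annotated MFAP2 transcripts, within ACCTCTGTCGGGACAAGTT, in the last exon at chromosome 1, 16975003 to 16975009, which is coding sequence in ENST00000375534 and ENST00000375535; 14.2% of all scanned sequences occur in MFAP2 transcripts. An effect of the MFAP2 siRNA on other transcripts through its seed is thus a candidate explanation for part of the lower genes, and GALNT7, HOXA10, NIPSNAP2, SYNGR2, ITGB1, TFAP2C and FOXF2 are among those with the sequence. The overlapping sequences ACAAGTA (t of -7.734), ACAAGTT (-6.936) and TGACAAG (-6.03) also lay below every permutation. The other 396 searched lower genes, among them CCND1, NOTCH1, NOTCH3 and MARCKSL1, hold no copy of GACAAGT in the 3′ UTR searched. Whether they hold the overlapping sequences was not counted, and other parts of the transcripts were not searched. A response to the loss of MFAP2 itself stays open as untested.

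The genes higher in siMFAP2 also share a sequence, more weakly. TCGGAGA had the highest t, 6.697 against a highest value of 5.368 in the permutations, and 31 of 501 searched higher genes (6.2%) held it, against 2.0% of genes not called. AGGAGAA, in 3220 UTRs, and GGAGAAA, in 2888, followed at 6.685 and 6.407, also above every permutation, so which of these sequences the higher genes share stays open. A seed effect of the control siRNA, relief from which could raise such genes in siMFAP2, is a candidate explanation for part of the higher genes. TPM4, HSDL2 and PCNX3 are among those with TCGGAGA. The size of that part is unknown, since higher genes with AGGAGAA or GGAGAAA were not counted. None of IFIT1, IFIT3, OASL, RSAD2, COL4A1 and CXCL8 holds TCGGAGA in the 3′ UTR searched, but they were not checked for AGGAGAA or GGAGAAA. The sequence of the control siRNA was not given in the sources used here.

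The interferon-stimulated genes were higher in siMFAP2, with 16 called. RNA from immune cells in the siMFAP2 libraries is argued against by 28 genes, those abundant in leukocytes and the immune cell markers together, whose median gain in mean FPKM was 0.0, against 3.26 for the 16 called genes; 12 of them, TYROBP, AIF1, CD53 and CD52 included, were listed at 0 in every library. CD68 and CD14 are among the 28 and were the 2 called higher of the 9 that passed the filter, and both, like ITGB2 and RAC2, were already above 1 FPKM in siCtrl, with RAC2 at 33.1 and 36.2 FPKM (limma adjusted p of 0.345). The scaling of the libraries, which would move every gene alike, is argued against by the log2 fold changes of all tested genes, whose median was -0.0178 and whose quartiles were -0.125 and 0.0881, against a median of 0.40 for the list. Whether the rise follows the loss of MFAP2 or the transfected siRNA itself stays open, since the knockdown and its siRNA are present in the same 3 libraries.

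Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many changed genes as the real one, which was the real split itself, and this held for the higher, lower and 2-fold genes. The real split gave 1152 changed genes against at most 4 in any other, 560 higher and 592 lower against at most 2 in the larger direction of any other, and 23 changed at least 2-fold against at most 4. With 10 splits the share cannot fall below 0.1, so this count is too small for a share under 0.05. Every other split mixes siCtrl and siMFAP2 libraries, so a difference between the groups adds to its within-group spread and lowers its calls. The contrast between the real split and the others is therefore no separate support.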
